A study of Mus musculus with 12 samples.

How the data were processed

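RNA was taken from 12 samples of the mouse T cell leukemia line 8946, 4 vector combinations with 3 libraries each, and libraries were made with the TruSeq mRNA v2 kit, which keeps no strand information. The deposited values are FPKM, 1 value per gene symbol and library, as the file names and headers state. The authors name FastQC 0.10.0, TopHat2 2.0.9, Bowtie2 2.1.0.0, Cufflinks, Cuffdiff 2.1.1 and the genome build mm10, without their order or settings. The gene annotation and any scaling between libraries inside these tools are not stated. The files hold no counts or read totals, so no counting interval is given. Relative depth was estimated from the steps between low FPKM values of 1174 genes, where a median of 46.0% of genes fell on a step.

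The table held 23284 gene symbols, of which 6449 were at 0 in all 12 libraries. Values were used as deposited, as log2(FPKM + 1), for the 10152 genes with a mean of at least 1 FPKM over the 12 libraries. Of these, 203 were at 0 in some library, and 196 of the 203 were short noncoding RNA genes, for which FPKM is imprecise. On this scale the fold changes of genes near or below 1 FPKM understate the ratio of means. Genes named by rule that lay under the filter were tested in a fit without it. Positions are those of GENCODE release M21 (GRCm38, equal to mm10), matched by symbol, and 9148 of the tested symbols (90.1%) had 1 position there.

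Groups followed the cell line label. The titles and column headers name the 2 single-vector groups the other way round, and the group names in the text follow the titles, whose vector genes were the ones raised. One limma model (version 3.58.1, R 4.3.3) held the 4 group means, with moderated variances and an intensity trend. It gave 6 pairwise comparisons and the interaction, each two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so significance rests on the variance that limma shares across genes. "Called", "rose" and "fell" refer to this threshold.

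Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 16 lists with at least 5 tested genes. They were Notch target genes, Notch pathway components, PIAS family, MYC target genes, T cell identity, cell cycle, cholesterol synthesis, glycolysis and hypoxia, amino acid and ER stress, interferon response, NF-kB response, p53 response, TGF-beta response, immediate early, integrin and migration, and replication-dependent histones. Smaller lists (early progenitor, B cell, myeloid, erythroid, fibroblast and NK cell markers, mitochondrial transcripts) give values only. The HIF target and ER chaperone lists of the closing sections were written after results had been seen. They were adjusted over these 2 lists alone. Named genes were, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap (predicted genes passed over), up to 4 members of each list with the largest change, and Notch1, Zmiz1, Ngfr, Hes1, Dtx1, Nrarp, Myc, Lef1, Ptcra, Il2ra and Notch3. Egln3 in combined against Notch1-titled libraries and the ER chaperones of the closing section lay outside this rule and were chosen after their values were seen. One gene that the rule names is not reported here. Overlaps were set against the product of the 2 call counts over the genes tested. For comparisons sharing controls, 100 simulations redrew all 12 libraries, the controls included, as unchanged groups with genes that varied independently.

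Alternatives were pseudocounts of 0.1 and 0.01, no filter or a filter at a mean of 5 FPKM, median ratio scaling, quantile normalization, the replicate number as a block, only the groups compared in the fit, robust variances, a 2-fold minimum, groups named by title, each library left out in turn, short noncoding RNA genes left out, and for lists an estimated correlation and fry. The pseudocount of 0.01, the leaving out of short noncoding RNA genes and the counts of called list members without each library were chosen after seeing the data. Where a group was left with 2 libraries, its spread was taken from the shared model. The pipeline was tested on simulated data of the same size with 200 changed genes: of 1.5-fold changes 79.1% were recovered in a pairwise comparison and 46.9% in the interaction, of 2-fold changes 96.4% and 88.1%, and 5.42% and 3.74% of calls were false. A list of 20 genes shifted by 0.3 was found in 100% of runs and 2% of unchanged lists were found (50 lists). The simulated genes varied independently, so this does not give the false rate for lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.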

Results

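Gene expression was measured by RNA sequencing in 12 libraries of the mouse T cell leukemia line 8946. Cells were transduced with a pair of retroviral vectors, one empty (MigR1) or carrying the Notch1 L1601P mutant with GFP, the other empty (NGFR) or carrying Zmiz1 with NGFR. Cells positive for both markers were sorted. Zmiz1 is a transcriptional coactivator of the PIAS-like family, and Notch1 is a receptor whose cleaved form activates transcription in T cell leukemia. The libraries formed 4 groups of 3. The sum of FPKM (fragments per kilobase of transcript, scaled to mapped fragments) per library lay between 549098 and 606908, and 14233 to 14554 genes were above 0. The files hold FPKM only, without read totals. The steps between low FPKM values placed the relative depth of the libraries between 0.749 (Zmiz1-titled replicate 2) and 1.21 (Notch1-titled replicate 1), so precision for genes near 0 FPKM is known only in relative terms. Zmiz1-titled replicate 2 also had the lowest mean correlation with the other libraries, 0.942 against up to 0.957.

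The 2 labels of the single-vector groups contradicted each other. Libraries titled Zmiz1 carried the cell line label L1601P/NGFR, and libraries titled Notch1 carried the cell line label MigR1/Zmiz1. The groups were fixed under the cell line label before the data were examined, as were the comparisons, tests, gene lists and alternatives except where stated. The genes of the vectors went with the titles, as did the deposited column headers. The groups are therefore named by their titles below as Zmiz1-titled (cell line label L1601P/NGFR), Notch1-titled (cell line label MigR1/Zmiz1), combined (L1601P/Zmiz1) and control (MigR1/NGFR). No library was moved between groups. Whether the 3 replicates of a group came from separate transductions or cultures is not stated, so each p measures only the spread between these libraries.

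Zmiz1 (chromosome 14, 25459185 to 25666743, GRCm38) averaged 0.176 ± 0.00489 FPKM in the control, 70.8 ± 3.39 in Zmiz1-titled, 0.212 ± 0.0153 in Notch1-titled and 49.3 ± 1.66 in combined libraries (mean ± SD, n = 3 per group here and throughout). Notch1 (chromosome 2, 26457903 to 26516663) averaged 1.89 ± 0.0863, 2.1 ± 0.218, 32.1 ± 10.1 and 35.6 ± 1.93 FPKM in the same order. Ngfr (chromosome 11, 95568818 to 95587735), the gene of the sorting marker, averaged 85.2 ± 3.25, 7.43 ± 0.248, 72.9 ± 10.1 and 5.64 ± 0.0183 FPKM. Zmiz1 rose in Zmiz1-titled libraries against the control (log2 fold change 5.93, limma adjusted p = 1.25e-13) and Ngfr fell by 3.35 (adjusted p = 4.90e-09), while Notch1 was not called (0.10, adjusted p = 0.875). Notch1 rose in Notch1-titled libraries against the control (3.47, adjusted p = 1.18e-06), while Zmiz1 (0.04, adjusted p = 0.73) and Ngfr (-0.23, adjusted p = 0.174) were not called. Under quantile normalization the Zmiz1 value was -0.39. In combined libraries Zmiz1 lay below its level in Zmiz1-titled libraries (log2 fold change -0.51, adjusted p = 3.12e-04), a call that quantile normalization ended. Notch1 in combined libraries differed from Notch1-titled libraries by 0.19 (adjusted p = 0.932), and the value was -0.05 without Notch1-titled replicate 3. The labels do not give the species or extent of the vector sequences, so these levels count only reads that aligned to the mouse genes.

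**Figure D1:**
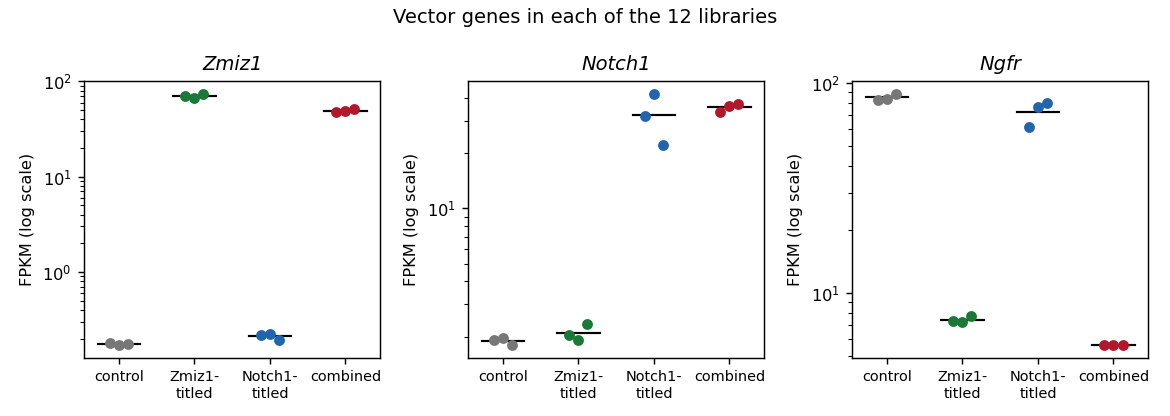
FPKM (log scale) of Zmiz1, Notch1 and Ngfr in each of the 12 libraries, with a line at each group's mean. Zmiz1 is high in Zmiz1-titled and combined libraries (means 70.8 and 49.3) and Notch1 in Notch1-titled and combined libraries (means 32.1 and 35.6).

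The comparison of Notch1-titled libraries with the control asked what the Notch1 mutant changed without added Zmiz1. Several known Notch target genes were higher. Ptcra, the pre-T cell receptor alpha chain, rose from 0.555 ± 0.152 to 5.29 ± 0.805 FPKM (log2 fold change 2.01, adjusted p = 4.89e-06). Trib2, a pseudokinase, rose from 11.5 ± 0.659 to 24.7 ± 1.71 FPKM (1.04, adjusted p = 2.20e-04). Dtx1, a Notch pathway ubiquitin ligase, was listed at 0 in the 3 control libraries and averaged 1.74 ± 0.221 FPKM, and Notch3 rose from 0.0681 ± 0.0265 to 1.60 ± 0.357 FPKM. Both lay under the filter on low values and were called in the fit without it (adjusted p = 9.44e-07 and 2.46e-05). Myc (chromosome 15, 61985391 to 61990374), a transcription factor of cell growth, rose from 0.0720 ± 0.0403 to 0.807 ± 0.0833 FPKM (0.75, adjusted p = 0.00140), a call that quantile normalization ended. Il7r, the interleukin-7 receptor, fell from 53 ± 2.59 to 29.6 ± 2.44 FPKM (-0.82, adjusted p = 1.71e-04). Il2ra was not called (0.25, adjusted p = 0.0549). Of 10 tested genes of the Notch target list 4 rose, 1 fell and 5 were not called, and the counts were 4 and 1 adjusted over the list alone. The list as a whole missed the threshold (camera adjusted p = 0.0558).

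**Figure D2:**
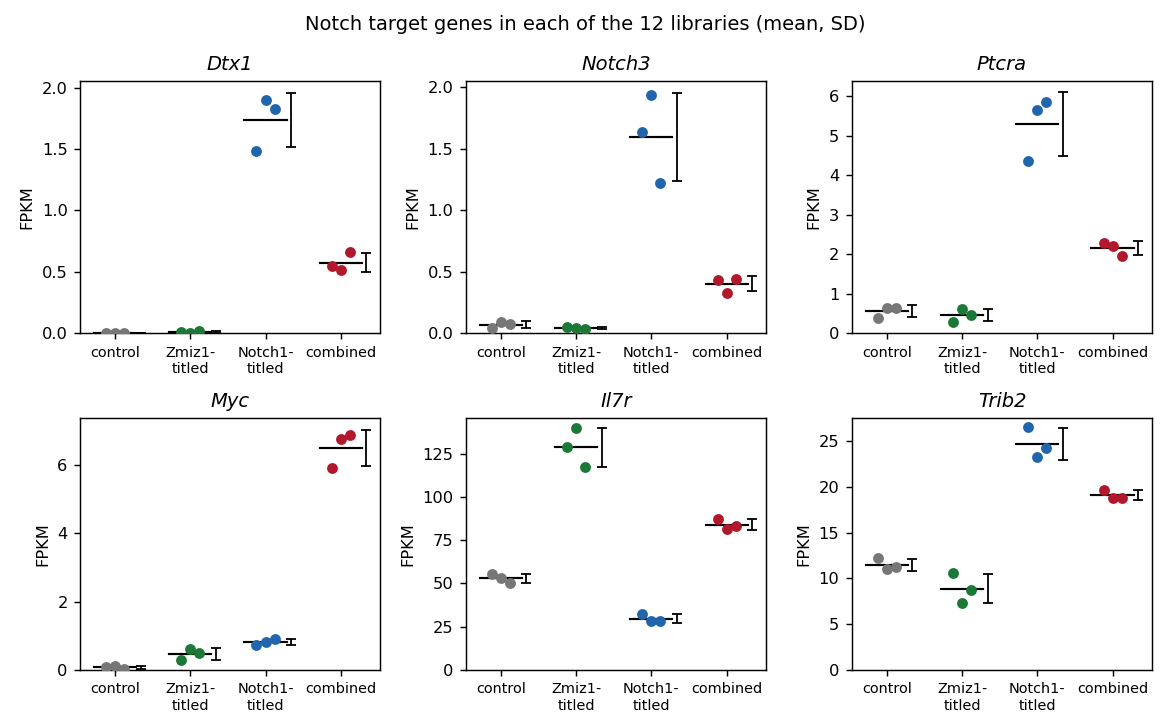
FPKM of Dtx1, Notch3, Ptcra, Myc, Il7r and Trib2 in each library (points), with group mean (line) and SD (bar). Dtx1, Notch3 and Ptcra are highest in Notch1-titled libraries, and Myc is highest in combined libraries (mean 6.51 FPKM).

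Glycolytic genes were also higher in Notch1-titled libraries than in the control. Of 17 tested genes of the glycolysis and hypoxia list 11 rose, 0 fell (0 of 17 also at an unadjusted p under 0.05 in limma) and 6 were not called, with 12 rising adjusted over the list alone (median 0.53, camera adjusted p = 7.63e-13). With an estimated correlation the list was at 0.0259. Aldoa, an aldolase, rose from 74.6 ± 1.98 to 193 ± 16.5 FPKM (log2 fold change 1.36). Pgk1, a phosphoglycerate kinase, rose from 173 ± 6.14 to 374 ± 5.62 FPKM (1.11), and Pkm2 rose by 0.80. Bnip3, a mitochondrial protein of cell death and mitophagy, rose from 7.51 ± 0.349 to 20.7 ± 1.78 FPKM (1.35). Tpi1, the triosephosphate isomerase, stood outside the list and rose by 1.49. Of 18 tested genes of the amino acid and ER stress list 11 rose and 7 were not called, with 12 rising adjusted over the list alone (median 0.43, adjusted p = 7.63e-13). Asns, the asparagine synthetase, rose from 1.82 ± 0.378 to 10.3 ± 0.783 FPKM (2.01, adjusted p = 1.04e-06). Mthfd2, an enzyme of mitochondrial folate metabolism, rose by 0.70. Hspa5, the main ER chaperone, rose from 149.6 ± 2.90 to 291 ± 7.38 FPKM (0.96), and Xbp1, a transcription factor of the unfolded protein response, rose by 0.73.

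Smaller shifts covered cell division and sterol synthesis. Of 24 cell cycle genes 7 rose and 17 were not called in Notch1-titled libraries against the control, with 14 rising adjusted over the list alone (median 0.23, camera adjusted p = 3.30e-08, and 0.0328 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 0.33 (adjusted p = 0.00857, and 0.0502 without control replicate 2). The count of 7 was 2, 0 and 1 without control replicate 1, 2 and 3, 12 without Zmiz1-titled replicate 2, 2 and 4 without Notch1-titled replicates 2 and 3, and 4 without combined replicate 2 or 3. Of 19 cholesterol synthesis genes 4 rose and 15 were not called, with 11 rising adjusted over the list alone (median 0.22, adjusted p = 2.24e-07, and 0.0328 with an estimated correlation). The count of 4 was 2, 1 and 1 without control replicates 1, 2 and 3, 2 without Notch1-titled replicate 2 and 8 without Zmiz1-titled replicate 2. The MYC target list was called with a median of 0.13 (adjusted p = 0.00202), a call lost at adjusted p = 0.231 with an estimated correlation. Its 1 called gene was Srm, the spermidine synthase (0.63, adjusted p = 0.0183, and 0.0544 to 0.0761 without any 1 control library or Notch1-titled replicate 2 or 3), and 4 genes were called without Zmiz1-titled replicate 2.

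Among single genes, Mecom (chromosome 3, 29951296 to 30548008), a transcription factor of blood stem cells, rose from 0.546 ± 0.0347 to 11.1 ± 0.478 FPKM (log2 fold change 2.97, adjusted p = 1.88e-08). Syne1 (chromosome 10, 5020917 to 5551482), a nuclear envelope spectrin repeat protein, fell from 7.40 ± 1.01 to 0.0232 ± 0.0165 FPKM (-3.03, adjusted p = 8.57e-06). The nonclassical MHC class I genes H2-T3, H2-T22, H2-Bl and H2-T10 rose by 2.19, 1.96, 1.91 and 1.59. These lie together on chromosome 17 between 36037128 and 36190287 and are similar in sequence, and reads shared between such paralogs make the level of each uncertain. Plac8 fell from 24.6 ± 1.53 to 8.86 ± 0.622 FPKM (-1.37), Gzma (granzyme A) from 644 ± 38.1 to 250.4 ± 26.2 (-1.36), and Etv5, an ETS family transcription factor, from 72.8 ± 1.13 to 31.8 ± 1.71 (-1.17). Cacna1b, Ly6c1, Cd53, Actn2, Itm2a and Slc6a19 fell by 1.10, 1.07, 1.0, 0.96, 0.93 and 0.92. Of 24 T cell identity genes 3 rose and 2 fell, 5 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.451). Cd6 rose by 0.65, Rag2, a subunit of the V(D)J recombinase, rose by 0.67 (adjusted p = 0.0103, and 0.0524 without control replicate 2), and the chemokine receptors Ccr9 and Ccr7 fell by 0.82 and 0.58. Snord83b, a small nucleolar RNA, was listed at 0 in the 3 control libraries and averaged 212 ± 133 FPKM (adjusted p = 0.0147, and 0.0535, 0.0574, 0.0562 and 0.0577 without control replicates 1, 2 and 3 and Notch1-titled replicate 2).

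In all, 324 genes rose and 233 fell of 10152 tested between Notch1-titled and control libraries (58.2% of calls up). The count of 557 was 291, 272 and 278 without control replicates 1, 2 and 3, 361 without Notch1-titled replicate 2 and 989 without Zmiz1-titled replicate 2. The split was 266 up and 287 down under median ratio scaling and 271 up and 300 down under quantile normalization.

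Combined against Zmiz1-titled libraries asked what the Notch1 mutant changed where Zmiz1 was added. Myc rose from 0.465 ± 0.165 to 6.51 ± 0.526 FPKM (log2 fold change 2.36, adjusted p = 6.48e-07). Asns rose from 2.26 ± 0.0496 to 14.0 ± 0.647 FPKM (2.20, adjusted p = 6.48e-07), and Hspa5 from 149.7 ± 26.2 to 398 ± 8.01 FPKM (1.42, adjusted p = 2.07e-05). Mecom rose from 0.632 ± 0.179 to 12 ± 0.464 FPKM (3.00), and Syne1 fell from 9.22 ± 3.75 to 0.0369 ± 0.0157 FPKM (-3.24). Ptcra and Trib2 rose by 1.12 and 1.04, Il7r fell by 0.61, and in the fit without the filter Dtx1 rose from 0.00821 ± 0.00843 to 0.574 ± 0.0781 FPKM (adjusted p = 1.40e-04). Notch3 (0.400 ± 0.0616 against 0.0425 ± 0.00730 FPKM, adjusted p = 0.0236) lost its call without any 1 library of either group, at 0.0702, 0.0602 and 0.0710 without Zmiz1-titled replicates 1, 2 and 3 and 0.0893, 0.0565 and 0.104 without combined replicates 1, 2 and 3. H2-T3, H2-T22 and H2-Bl rose by 2.67, 2.17 and 2.13. Sdf2l1, an ER protein of the chaperone complex, rose from 16.5 ± 3.19 to 63.6 ± 0.889 FPKM (1.90). Genes that fell included Ccr8 (13.3 ± 1.92 to 3.78 ± 0.445 FPKM, -1.58), Mab21l2 (-1.04), Gzma (-1.0), Ccr9 (-0.89), Ly6c1 (-0.89), Insl5 (-0.88), Wfs1 (-0.87), Etv5 (-0.86) and Itm2a (-0.83).

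Of 18 amino acid and ER stress genes 11 rose in combined against Zmiz1-titled libraries, 7 were not called, and 13 rose adjusted over the list alone (median 0.58, camera adjusted p = 4.22e-16). Shmt2, a mitochondrial serine hydroxymethyltransferase, rose by 1.05 and Xbp1 by 0.90. Of 30 MYC target genes 8 rose and 22 were not called, with 16 rising adjusted over the list alone (median 0.22, adjusted p = 2.47e-11, and adjusted p = 0.0698 with an estimated correlation). Srm rose by 1.05 and Cad, which starts pyrimidine synthesis, by 0.66. The count of 8 was 5, 4 and 4 without control replicates 1, 2 and 3, 5 without Zmiz1-titled replicate 1, 5 without Notch1-titled replicate 2, and 4, 3 and 3 without combined replicates 1, 2 and 3. The Notch target list (4 rose, 1 fell, 2 falling without Zmiz1-titled replicate 3) was called at 0.00487, lost at adjusted p = 0.0733 with an estimated correlation. The glycolysis list, with 1 called gene, Pgam1 (0.42), was called at 0.00459, lost at adjusted p = 0.270 with an estimated correlation. Its count was 2 without Zmiz1-titled replicate 1, Notch1-titled replicate 1 or 3 or combined replicate 1, and 2 rising and 2 falling without Zmiz1-titled replicate 2. The cholesterol list was called at 0.00643 and the p53 response list at 0.0186, both lost at adjusted p = 0.226 with an estimated correlation. In all, 271 genes rose and 121 fell (69.1% up), against 228 up and 159 down under median ratio scaling. The count of 392 was 250, 187 and 184 without combined replicates 1, 2 and 3, and 155 with only the groups compared in the fit.

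**Figure D3:**
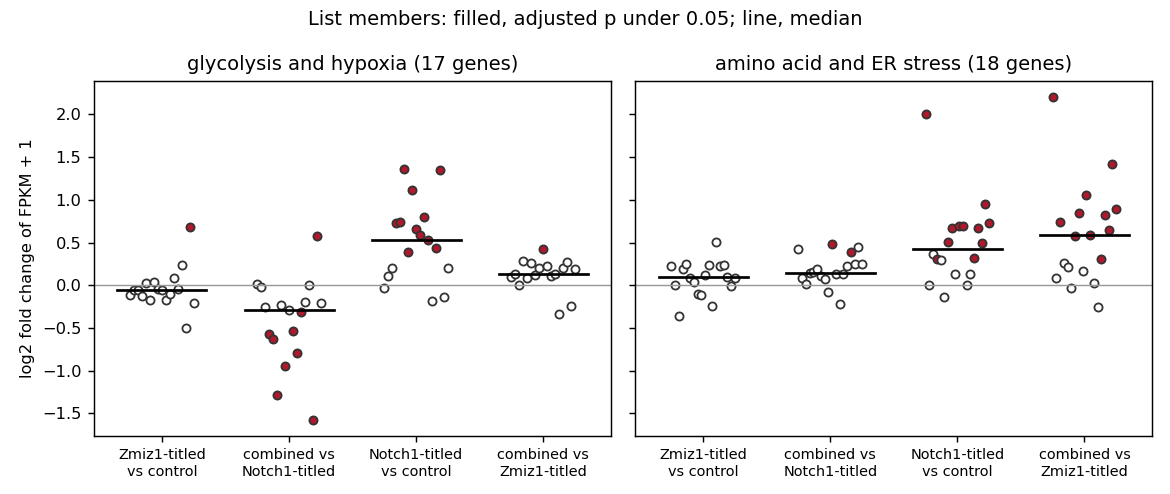
Log2 fold changes of the 17 glycolysis and hypoxia genes and the 18 amino acid and ER stress genes in 4 comparisons; filled points passed an adjusted p of 0.05 and lines mark medians. The glycolysis median was 0.53 in Notch1-titled against control libraries and -0.29 in combined against Notch1-titled libraries.

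Zmiz1-titled against control libraries asked what Zmiz1 changed without the Notch1 mutant. Ccr8, a chemokine receptor, rose from 0.478 ± 0.105 to 13.3 ± 1.92 FPKM (log2 fold change 3.27, adjusted p = 4.14e-08). Gzma rose from 644 ± 38.1 to 2253 ± 129.7 FPKM (1.81, adjusted p = 5.30e-07), Etv5 from 72.8 ± 1.13 to 179 ± 6.20 (1.29) and Il7r from 53 ± 2.59 to 129 ± 11.5 (1.26). Wfs1, an ER membrane protein, rose by 2.13, Prkaa2, a catalytic subunit of AMPK, by 1.74, Ppap2b by 1.67, Sytl3 by 1.63 and Tmem158 by 1.21. Gpr56, an adhesion receptor, fell from 16.8 ± 0.173 to 7.40 ± 0.398 FPKM (-1.08). H2-Oa, an MHC class II-like chain, fell by 0.88, Gsta4 by 0.86, Cd7 by 0.86, Nsg2 by 0.85, Tmem45a by 0.84, Slfn2 by 0.83 and Prr5 by 0.83. Myc (0.465 ± 0.165 against 0.0720 ± 0.0403 FPKM, 0.44, adjusted p = 0.0511) and Ptcra (-0.10, adjusted p = 0.793) were not called. The small nucleolar RNA Snora2b fell from 41.4 ± 25.5 to 4.12 ± 7.13 FPKM (adjusted p = 0.0385), and its adjusted p was 0.0538 to 0.175 without any 1 library other than Zmiz1-titled replicate 1.

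List changes in Zmiz1-titled against control libraries were small, and each of the 5 called lists was lost with an estimated correlation. Of 24 cell cycle genes 0 passed in limma and 8 had an unadjusted p under 0.05, all 8 of them higher, and 23 of the 24 fold changes were positive (median 0.13, camera adjusted p = 2.13e-05, and adjusted p = 0.0897 with an estimated correlation). Of 11 interferon response genes 0 passed, 5 had an unadjusted p under 0.05, and 4 fell adjusted over the list alone (median -0.21, adjusted p = 2.94e-04, and 0.0897 with an estimated correlation). The count of 0 that passed over all genes was 1 without Zmiz1-titled replicate 3, Notch1-titled replicate 1 or combined replicate 1, and 2 without Notch1-titled replicate 3. Of 24 T cell identity genes 1 rose and 4 fell (2 and 5 adjusted over the list alone), and the list was called at 0.00191, lost at adjusted p = 0.0897 with an estimated correlation. Ccr7 fell by 0.68. The count of 4 was 2 or 1 without any 1 control library, any 1 Zmiz1-titled library or combined replicate 2 or 3. Of 10 Notch target genes Il7r and Gata3 rose, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.00588, and 0.0897 with an estimated correlation). Gata3, a T cell transcription factor, rose by 0.72 (adjusted p = 0.0150, and 0.0746 and 0.0822 without control replicates 2 and 3), and without Zmiz1-titled replicate 1 the list held 3 rising genes and 1 falling gene. The amino acid and ER stress list (0 of 18 called in limma, 9 at an unadjusted p under 0.05) was called at 0.0433, lost at adjusted p = 0.127 with an estimated correlation. In all, 109 genes rose and 105 fell. The count of 214 was 106, 81 and 74 without control replicates 1, 2 and 3, 121 with the filter at a mean of 5 FPKM and 49 with only the groups compared in the fit.

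Combined against Notch1-titled libraries asked what Zmiz1 changed where the Notch1 mutant was present. Myc rose from 0.807 ± 0.0833 to 6.51 ± 0.526 FPKM (log2 fold change 2.05, adjusted p = 1.50e-06). Gzma rose from 250.4 ± 26.2 to 1127 ± 36.7 FPKM (2.17), Il7r from 29.6 ± 2.44 to 84.1 ± 3.16 (1.48) and Etv5 from 31.8 ± 1.71 to 98.6 ± 4.46 (1.60). Other Notch target genes went the other way. Ptcra fell from 5.29 ± 0.805 to 2.15 ± 0.170 FPKM (-0.99, adjusted p = 0.00181). In the fit without the filter Dtx1 fell from 1.74 ± 0.221 to 0.574 ± 0.0781 FPKM (-0.80, adjusted p = 5.71e-05) and Notch3 from 1.60 ± 0.357 to 0.400 ± 0.0616 (-0.88, adjusted p = 5.82e-04). The call on Dtx1 ended with a pseudocount of 0.01 and that on Notch3 with only the groups compared in the fit. Of 10 tested genes of the Notch target list 2 rose, 1 fell and 7 were not called, with 4 rising and 2 falling adjusted over the list alone. Without Zmiz1-titled replicate 2 these counts were 3 and 2. The list as a whole was called upward (median 0.15, camera adjusted p = 0.00123), opposite to Ptcra, Dtx1 and Notch3. Dtx1 and Notch3 lay under the filter and were not among its tested genes. Ccr8, Wfs1, Prkaa2 and St3gal2 rose by 1.94, 1.51, 1.28 and 1.22. Stc1, a secreted glycoprotein, rose by 1.27 (adjusted p = 0.0118, and 0.0583, 0.0548, 0.0657 and 0.0609 without Notch1-titled replicates 2 and 3 and combined replicates 1 and 3). Tmem45a, Ampd1 and Gpr56 fell by 1.22, 0.94 and 0.86.

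Glycolytic genes fell in combined against Notch1-titled libraries. The fall set in from the raised level of the Notch1-titled libraries, and the list median was 0.08 in combined against control libraries. Of 17 tested genes 8 fell, 1 rose and 8 were not called, with 11 falling and 1 rising adjusted over the list alone (median -0.29, camera adjusted p = 2.55e-16). Aldoa fell from 193 ± 16.5 to 78.9 ± 4.51 FPKM (-1.28), Pgk1 from 374 ± 5.62 to 194 ± 9.14 (-0.95) and Bnip3 from 20.7 ± 1.78 to 6.29 ± 0.584 (-1.57). Pkm2 fell by 0.79, and outside the list Tpi1 fell by 1.22 and Slc16a3, a lactate transporter, by 1.36. Egln3, a prolyl hydroxylase that acts on HIF, was the gene that rose (0.58). The MYC target list was called with a median of 0.13 (adjusted p = 3.07e-08, and 0.0485 with an estimated correlation), although 1 of 30 genes, Srm, passed and 7 did adjusted over the list alone. Srm (0.62, adjusted p = 0.0447) lost its call, at up to 0.193, without any 1 library other than Zmiz1-titled replicates 1 and 2 and Notch1-titled replicate 3, and 3 genes were called without Zmiz1-titled replicate 2. The amino acid and ER stress list (median 0.15, adjusted p = 2.81e-07) held 2 called genes, both rising, and 7 rising and 1 falling adjusted over the list alone. The count of 2 was 1 without Notch1-titled replicate 2 or 3 or any 1 combined library, 3 without control replicate 3 and 4 without Zmiz1-titled replicate 2. Shmt2 rose by 0.49. The T cell identity (median -0.13, adjusted p = 3.63e-05), cholesterol (-0.15, adjusted p = 7.42e-05) and interferon lists (-0.17, adjusted p = 1.42e-04) were also called. With an estimated correlation they were at 0.0395, 0.0485 and 0.0485. Cd6 fell by 0.75 and Ifi27l2a, an interferon-induced gene, by 0.59. The immediate early list (0 of 7 called in limma, 3 at an unadjusted p under 0.05, and 2 called without Zmiz1-titled replicate 2) was called at 0.0237, lost at adjusted p = 0.224 with an estimated correlation. In all, 84 genes rose and 69 fell. The count of 153 was 306 without Zmiz1-titled replicate 2, 85 without Notch1-titled replicate 2, 75, 93 and 80 without combined replicates 1, 2 and 3, and 101 with the filter at a mean of 5 FPKM.

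Combined against control libraries gave the effect of both vectors together. Myc rose from 0.0720 ± 0.0403 to 6.51 ± 0.526 FPKM (log2 fold change 2.81, adjusted p = 7.28e-08), and Asns from 1.82 ± 0.378 to 14.0 ± 0.647 (2.43, adjusted p = 1.52e-07). Of 10 Notch target genes 5 rose, 0 fell (0 also at an unadjusted p under 0.05 in limma) and 5 were not called, with 6 rising adjusted over the list alone (median 0.39, camera adjusted p = 4.09e-09). Ptcra rose by 1.02, Trib2 by 0.69 and Il7r by 0.66. Under the filter, Il2ra averaged 0.606 ± 0.0963 FPKM against 0.279 ± 0.0206 (adjusted p = 0.0133, and 0.0585 and 0.0552 without control replicate 3 and combined replicate 2), and Dtx1 averaged 0.574 ± 0.0781 FPKM against 0 in the 3 control libraries (adjusted p = 1.16e-04). Of 18 amino acid and ER stress genes 11 rose, and 13 rose and 1 fell adjusted over the list alone (median 0.58, adjusted p = 7.42e-16), with Hspa5, Shmt2 and Slc7a5, an amino acid transporter, up by 1.41, 1.18 and 1.06. Of 30 MYC target genes 10 rose and 13 did adjusted over the list alone (median 0.24, adjusted p = 8.85e-11, and 0.0490 with an estimated correlation). Srm rose from 2.1 ± 0.101 to 6.43 ± 0.499 FPKM (1.26), and Cad rose by 0.67.

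Of 24 cell cycle genes 5 rose in combined against control libraries and 12 did adjusted over the list alone (median 0.20, camera adjusted p = 3.28e-07). With an estimated correlation the list was at 0.0490. The count of 5 was 2, 1 and 0 without control replicates 1, 2 and 3, 3 and 2 without Notch1-titled replicates 1 and 2, and 2, 0 and 0 without combined replicates 1, 2 and 3. The interferon (adjusted p = 0.0179, and 0.237 with an estimated correlation), T cell identity (0.0383, and 0.237 with an estimated correlation), glycolysis (0.0422, and 0.359 with an estimated correlation) and cholesterol lists (0.05, and 0.338 with an estimated correlation) were called with the preset correlation and by fry but not with an estimated correlation. Mecom, H2-T3, Cox6a2 and H2-Bl rose by 3.08, 2.1, 1.97 and 1.91. Nfkbie, an NF-kB inhibitor, rose by 1.37 and Gzma by 0.81. Syne1 fell by 3.01, Plac8 by 1.08, Ly6c1 by 1.07, Alox5ap by 1.04, Epsti1 by 1.03, Sh3bgrl2 by 0.98, H2-Oa by 0.89, P4ha2 by 0.87, H2-Eb2 by 0.85 and Ccr7 by 0.83. In all, 403 genes rose and 253 fell (61.4% up), against 332 up and 358 down under quantile normalization. The count of 656 was 379, 339 and 349 without control replicates 1, 2 and 3, 1090 without Zmiz1-titled replicate 2, 405, 349 and 355 without combined replicates 1, 2 and 3, and 1386 with only the groups compared in the fit.

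Zmiz1-titled and Notch1-titled libraries, which carried 1 vector gene each, differed in 1109 genes, the highest pairwise count in the fit of all 4 groups. Ccr8 was 13.3 ± 1.92 FPKM in Zmiz1-titled against 0.243 ± 0.0142 in Notch1-titled libraries (log2 fold change 3.52, adjusted p = 9.63e-09), and Gzma was 2253 ± 129.7 against 250.4 ± 26.2 (3.17, adjusted p = 2.45e-09). Syne1, Etv5, Wfs1, Il7r, Itm2a, Prkaa2 and Actn2 were higher by 3.26, 2.46, 2.39, 2.09, 2.04, 2.01 and 1.78. Mecom, H2-T3, H2-T22, H2-Bl, H2-T10, Ptcra and Bnip3 were lower, with values of -2.90, -2.76, -2.41, -2.13, -1.87, -2.11 and -1.85. Of 24 T cell identity genes 10 were lower and 1 higher in Zmiz1-titled libraries, 13 and 2 adjusted over the list alone (camera adjusted p = 0.0115, and 0.161 with an estimated correlation), and 2 were higher without Zmiz1-titled replicate 1 or 2. Cd6, Cd2 and Lck, the kinase of the T cell receptor, had values of -1.05, -0.58 and -0.55, and Ccr9 had 1.53. Glycolysis genes were lower in 11 of 17 and higher in 1 (14 and 1 adjusted over the list alone, median -0.44, adjusted p = 1.18e-09, and 0.0541 with an estimated correlation). Amino acid and ER stress genes were lower in 12 of 18, with 12 lower and 1 higher adjusted over the list alone (median -0.41, adjusted p = 1.25e-07), and 1 was higher without Notch1-titled replicate 1. Cholesterol genes were lower in 9 of 19, with 14 lower and 1 higher adjusted over the list alone (adjusted p = 2.06e-05, and 0.0760 with an estimated correlation), among them Sqle (-0.50), and 1 was higher without Zmiz1-titled replicate 1 or Notch1-titled replicate 2. The interferon (3 of 11 lower, adjusted p = 0.00468, and 0.161 with an estimated correlation), MYC target (0.0392, and 0.384 with an estimated correlation) and p53 lists (0.0441, and 0.279 with an estimated correlation) were called with the preset correlation. In all, 443 genes were higher and 666 lower in Zmiz1-titled libraries (39.9% higher), against 531 and 524 under median ratio scaling. The count of 1109 was 266 with only the groups compared in the fit, where it ranked below combined against control (1386) and Notch1-titled against control (424).

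The interaction asked whether the joint effect differed from the sum of the single effects on the log2 scale, and 7 of 10152 genes passed. Myc gained 1.61 ± 0.142 (log2 ± SE, adjusted p = 0.00190). Plac8 gained 0.98 ± 0.0921 (adjusted p = 0.00194): Zmiz1 went with a lower level without the Notch1 mutant (24.6 ± 1.53 to 15.0 ± 0.231 FPKM) and a higher one with it (8.86 ± 0.622 to 11.1 ± 0.555). Pgk1 and Aldoa, which rose with the Notch1 mutant alone, had interactions of -0.91 ± 0.0821 (adjusted p = 0.00190) and -1.10 ± 0.121 (adjusted p = 0.00633), and Tpi1 had -1.10 ± 0.160 (adjusted p = 0.0464). Ccr8 had -1.33 ± 0.153 (adjusted p = 0.00735) and Zmiz1 itself -0.56 ± 0.0747 (adjusted p = 0.0266). Zmiz1 averaged 70.8 FPKM in Zmiz1-titled and 49.3 in combined libraries, so the interaction does not compare equal Zmiz1 levels. In the fit without the filter Dtx1 (-0.81, adjusted p = 0.00262) and Notch3 (-0.85, adjusted p = 0.0310) were also called, and Ptcra was not (-0.89, adjusted p = 0.305). Dtx1 and Notch3 lay near 0 FPKM without the Notch1 mutant and could hardly fall there. Their interactions mostly restate their fall in combined against Notch1-titled libraries. The values are changes of log2(FPKM + 1), which compresses fold changes of genes near 0 FPKM. For Myc the ratio of means with and without Zmiz1 was 6.46 without the Notch1 mutant and 8.07 with it, and with a pseudocount of 0.1 its interaction was 1.17 with an adjusted p of 1. With the same pseudocount the calls on Ccr8, Zmiz1 and Tpi1 ended (adjusted p = 0.535, 0.0622 and 0.0622), while Pgk1, Aldoa and Plac8 were still called. The values of Zmiz1 and Tpi1 did not shrink, at -0.70 and -1.11, while that of Ccr8 was -1.05. Of 17 glycolysis genes 2 passed and 10 did adjusted over the list alone, all with negative values (median -0.27, camera adjusted p = 1.34e-20). The cell cycle (median -0.14, adjusted p = 1.10e-08, and 0.0529 with an estimated correlation), MYC target (0.11, adjusted p = 9.62e-07, and 0.127 with an estimated correlation), cholesterol (-0.11, adjusted p = 0.00110, and 0.127 with an estimated correlation) and amino acid and ER stress lists (0.09, adjusted p = 0.00351, and 0.0626 with an estimated correlation) held 0 called genes in limma and 2, 6, 1 and 2 at an unadjusted p under 0.05.

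Genes called for Zmiz1 with or without the Notch1 mutant mostly had the same direction in both settings, although 91 of 276 were called in both. Of the genes called in Zmiz1-titled against control and in combined against Notch1-titled libraries, which share no library, 59 rose in both and 32 fell in both. For independent calls n1·n2/N gives 0.902 and 0.714. The calls are not fully independent, since both comparisons use the same variance per gene from 1 fit. Across the 276 genes called in either, the fold changes correlated at r = 0.859 and rho = 0.822 (r = 0.805 without the vector genes), and 96.0% had the same sign. These genes were selected by their calls, and across all tested genes r was 0.114. Genes are not independent replicates, so no p is given. Both comparisons raised Gzma, Ccr8, Etv5, Il7r, Wfs1 and Prkaa2 and lowered Gpr56 and Tmem45a. The count of 91 shared calls was 53 and 54 without control replicates 2 and 3, 147 without Zmiz1-titled replicate 2, 57 without Notch1-titled replicate 2 and 51, 58 and 54 without combined replicates 1, 2 and 3. For the Notch1 mutant with and without Zmiz1, 163 genes rose in both comparisons and 83 fell in both, where n1·n2/N gives 8.65 and 2.78. Across the 703 genes called in either, r was 0.854 and rho 0.839, with 98.3% of one sign, and r was 0.191 across all tested genes. Mecom, Asns, H2-T3, Ptcra, Trib2 and Hspa5 rose in both, and Syne1, Gzma, Etv5, Il7r and Ly6c1 fell in both. A common clonal origin of the Notch1-vector cells, taken up in a closing section, would also give shared changes. The overlap alone therefore cannot tell such an origin from a response to the mutant. The count of 246 was 157 without control replicate 2 and 143 and 141 without combined replicates 2 and 3.

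**Figure D4:**
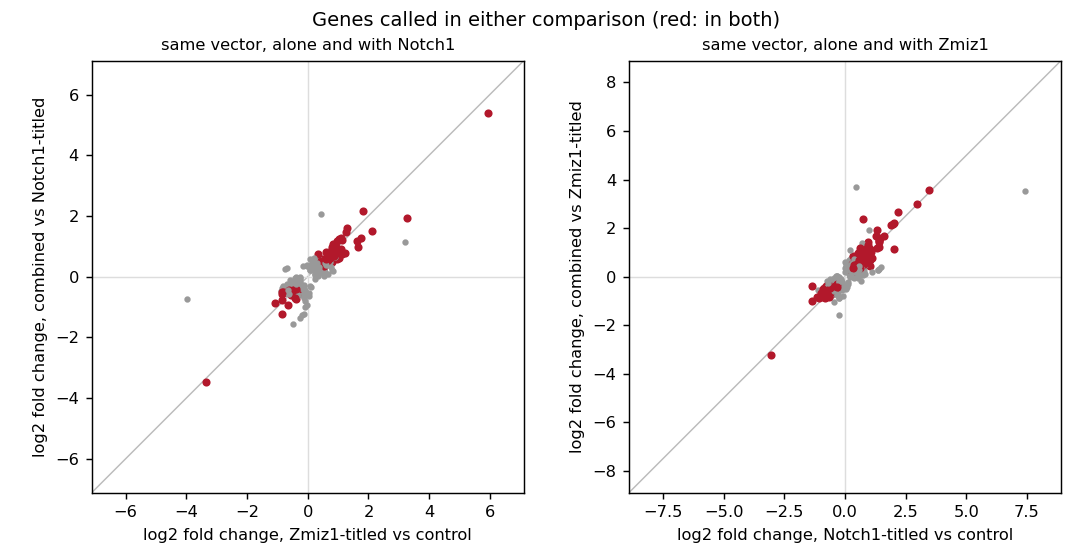
Log2 fold changes of genes called in either of 2 comparisons that share no library, for Zmiz1 (left) and the Notch1 mutant (right), each without and with the other vector gene; red points were called in both. The left panel holds 276 genes and the right panel 703.

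The 2 single-vector comparisons share the 3 control libraries. Zmiz1-titled and Notch1-titled libraries both raised 6 genes and both lowered 21 against the control (3.48 and 2.41 by n1·n2/N). Another 24 rose with Zmiz1 and fell with Notch1, and 12 fell and rose (2.5 and 3.35 by n1·n2/N). These expected counts take the 2 comparisons as independent, which shared controls prevent. Il7r, Gzma and Etv5 were among the 24, and Ccr7 was among the 21. The count of 27 with the same sign was 11, 6 and 6 without control replicates 1, 2 and 3, 50 without Zmiz1-titled replicate 2 and 15 without combined replicate 2. Across all genes r was 0.345, against 0.372 to 0.621 (mean 0.492) in 100 simulations of unchanged groups that shared simulated controls. In the data 53.5% of genes had the same sign, against 65.5% to 67.6% in the simulations. Real changes in 1 group only or in opposite directions lower both values, and changes in the same direction can raise them. The simulated genes also varied independently. Neither value can therefore tell whether the effects of the 2 vectors were opposed. The covariance of 0.0420 lay within the simulated range (0.0268 to 0.0552, mean 0.0396).

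Other lists gave no call by camera in any comparison. These were the Notch pathway components (1 of 20 genes called in 1 comparison, Adam17 between the single-vector groups, lost at up to 0.120 without any 1 control or combined library or Notch1-titled replicate 2 or 3), the PIAS family, the NF-kB and TGF-beta responses, integrins and migration, and replication-dependent histones (0 of 10 called in limma in any comparison, at most 3 at an unadjusted p under 0.05, and 1 called in some comparisons without control replicate 2 or Zmiz1-titled replicate 2). Where a list's median, mean and test differed in sign, that list was not called. Among PIAS genes Pias3 passed in Notch1-titled against control libraries (-0.29, adjusted p = 0.0349), a call lost at 0.0559 to 0.144 without any 1 control library, Notch1-titled replicate 1 or 2, or combined replicate 2 or 3. Of markers of other cell types, 0 of 13 B cell genes passed the filter, 1 myeloid gene did (Itgam), 1 erythroid gene (Epor), 1 fibroblast gene (Fstl1), 2 NK cell genes (Gzma and Prf1) and 2 early progenitor genes (Cd44 and Runx2). Itgam, an integrin of myeloid cells, fell from 99.5 ± 2.08 to 55.7 ± 4.12 FPKM in Notch1-titled against control libraries (-0.83), and Runx2 fell by 0.53. Epor passed only between Zmiz1-titled and Notch1-titled libraries (-0.72), and Fstl1 passed in no comparison. The mitochondrial transcripts were not in the deposited table. Hes1, a main Notch target in many tissues, was listed at 0 in all 12 libraries, Nrarp averaged 0.186 to 0.256 FPKM per group, and Lef1 averaged 55.5 to 63.8 FPKM and was not called in any comparison. Of 16 lists tested, the calls that also held with an estimated correlation were 0 of 5 in Zmiz1-titled against control, 7 of 8 in combined against Notch1-titled, 4 of 5 in Notch1-titled against control, 1 of 6 in combined against Zmiz1-titled, 4 of 8 in combined against control, 1 of 7 between the single-vector groups and 1 of 5 in the interaction. The list that held in combined against Zmiz1-titled libraries and between the single-vector groups was amino acid and ER stress, and in the interaction it was glycolysis and hypoxia.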

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

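The tests of vector genes per library, of neighboring genes, of level ratios and gaps, of the glycolysis median under other scalings, and of HIF targets were chosen only after the result was seen. The effect of Zmiz1 with the Notch1 mutant differed from its effect without it, by the interaction test, for 7 genes: log2 values of 1.61 for Myc, -0.91 for Pgk1, 0.98 for Plac8, -1.10 for Aldoa, -1.33 for Ccr8, -0.56 for Zmiz1 and -1.10 for Tpi1. Zmiz1 itself was lower in combined (49.3 FPKM) than in Zmiz1-titled libraries (70.8 FPKM), and what part this had in the other values was not tested. With pseudocounts of 0.1 and 0.01 the calls on Myc (adjusted p = 1 with both), Ccr8 (0.535 and 1), Zmiz1 (0.0622 and 0.0741) and Tpi1 (0.0622 and 0.0703) ended. The values of Myc (1.17 and 0.38) and Ccr8 (-1.05 and -0.89) shrank. Those of Zmiz1 (-0.70 and -0.78) and Tpi1 (-1.11 with both) did not. The ratio of Myc means with and without Zmiz1 was 6.46 without the Notch1 mutant and 8.07 with it. By the list test it differed for 5 lists, with median interactions of -0.27 for glycolysis and hypoxia, -0.14 for the cell cycle, 0.11 for MYC targets, -0.11 for cholesterol synthesis and 0.093 for amino acid and ER stress. With an estimated correlation only glycolysis and hypoxia was still called (adjusted p = 0.0111), while the cell cycle was at 0.0529, amino acid and ER stress at 0.0626, and MYC targets and cholesterol synthesis at 0.127. Deviations of the libraries from the additive fit were arranged in 100 ways. Only 1 of them, the real one, gave as many as 7 calls, and the highest other gave 4. Arrangements were made for the main fit only, and the real count was 3 with either other pseudocount and 4 under quantile normalization. How the replicates arose is not stated, so chance differences between cultures cannot be excluded. For the pairwise counts 3 against 3 libraries make 10 splits, too few for a share under 0.05, with 1 of 10 (the real split) as large in each. The real and the highest other counts were 214 and 2 for Zmiz1-titled against control, 153 and 1 for combined against Notch1-titled, 557 and 1 for Notch1-titled against control, 392 and 1 for combined against Zmiz1-titled, 656 and 2 for combined against control, and 1109 and 2 between the single-vector groups.

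The first pattern is the label conflict of the single-vector groups. In 6 of the 6 single-vector libraries the raised vector gene was the one in the title, at over 10 times the highest control library, and in 0 of 6 was it the one in the cell line label, which argues against an exchange of single libraries. An exchange of the 2 cell line labels as a whole is consistent with these values and remains open as the likely reading. A change of the vectors themselves before labelling was not tested. If the labels are exchanged, the count of 557 belongs to the Notch1 mutant and that of 214 to Zmiz1, as in the group names used here.

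The second pattern is Syne1 and Mecom in libraries with the Notch1 vector. Syne1 lay between 0.0116 and 0.0550 FPKM in these 6 libraries and between 6.27 and 13.5 in the others, a gap of 114-fold, where the gene with the next widest gap downward, Ly6c1, reached 1.5-fold. The values argue against a change that spans the neighboring genes, since 0 of the 12 other tested genes within 1 Mb of Syne1 or Mecom were called. A change of the DNA confined to Syne1 or to Mecom would leave those neighbors as they were, so this count cannot exclude it. A response graded with Ptcra, Notch3 and Dtx1 was also argued against for Mecom, whose combined level was 1.08 times the Notch1-titled level, where these were at 0.407, 0.250 and 0.331. A response graded with the Notch1 level itself stays open, since Notch1 was at 1.11, and other genes raised by the mutant differed, with Asns at 1.37 and Myc at 8.07. A common clonal origin of the Notch1-vector cells, whose Syne1 was over 10 times below the lowest other library in 6 of 6, cannot be told apart from a response to the mutant, because both cover the same libraries.

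The third pattern is the glycolysis list, which rose with the Notch1 mutant alone and had a negative interaction. The rise, the fall in combined libraries and the interaction all rest on the same Notch1-titled libraries. Against the control the list median was 0.53 in these, -0.05 in Zmiz1-titled and 0.08 in combined libraries. The values cannot separate an effect of Zmiz1 on the response to the mutant from a difference of the Notch1-titled group alone. The list's median interaction was at most -0.26 under median ratio scaling and quantile normalization. Over all genes the median was 0.0005 in the main fit and 0.004 and 0.0087 under these scalings. They could therefore hardly have moved the list. A uniform scaling difference would shift all genes, and the value of 0.0005 argues against it. Any 1 library as the cause was also argued against, with a highest median interaction of -0.24 (without Notch1-titled replicate 3) and a lowest of -0.33. A wider response to HIF, the hypoxia factor, stays open: the median of 15 HIF targets outside glycolysis was 0.06 in Notch1-titled against control libraries, with a bootstrap SD of 0.15, although 5 of them rose and the list was called there (adjusted p = 0.0308, and just under 0.05 with an estimated correlation). The HIF list was also called in the interaction (median -0.17, adjusted p = 0.00151 with an estimated correlation) and in combined against Notch1-titled libraries (median -0.26, 3 fell, adjusted p = 3.15e-04 with an estimated correlation). All these comparisons use the same Notch1-titled libraries, so the calls are not separate evidence. Without that group camera gave no call. The medians were -0.07 in Zmiz1-titled against control, 0.03 in combined against Zmiz1-titled and -0.04 in combined against control libraries. A biological difference between the groups may also remain, such as the growth state of the cultures, and was not tested.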

How the results depend on the processing

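The pseudocount of 0.01 and the leaving out of short noncoding RNA genes were chosen only after the results were seen, and the other alternatives were planned. Counts below are of called genes in the order Zmiz1-titled against control, combined against Notch1-titled, Notch1-titled against control, combined against Zmiz1-titled, combined against control, single-vector groups and interaction. Read totals are unknown, so depth limits genes near 0 FPKM by an amount that cannot be given.

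With each library left out the counts were 74 to 241, 75 to 306, 272 to 989, 184 to 505, 339 to 1090, 765 to 1110 and 5 to 8. The filter at 5 FPKM, which tests fewer genes, gave 121, 101 and, for the interaction, 3. No filter gave 18 for the interaction. Pseudocounts of 0.1 and 0.01 gave 3 each and quantile normalization 4 there. A 2-fold minimum gave 22, 20, 37, 39, 52, 85 and 4, by its construction. With only the groups compared in the fit, which estimates the spread from fewer libraries, the counts were 49 for Zmiz1-titled against control, 155 for combined against Zmiz1-titled, 1386 for combined against control and 266 for the single-vector groups. Naming groups by title instead of by the cell line label exchanges which vector gene a count belongs to. For the Notch1 mutant alone the count was 214 by the cell line label and 557 by the title, and for Zmiz1 alone 557 and 214. For the Notch1 mutant where Zmiz1 was added it was 153 by the cell line label and 392 by the title. For Zmiz1 where the mutant was present it was 392 and 153. Shared calls moved from 91, 246 and 27 to 51 to 147, 141 to 335 and 6 to 50 without each library. List calls with an estimated correlation were 0 for Zmiz1-titled against control, 1 for combined against Zmiz1-titled, 4 for combined against control, 1 for the single-vector groups and 1 for the interaction. With fry they were 12 and 1 for the latter 2 (which asks whether a list's genes move one way, not whether they move more than others). Without each library the list calls by camera at the preset correlation were 4 to 6, 7 to 9, 5 to 7, 6 to 7, 4 to 8, 5 to 8 and 5 to 5. Where no construction is named, the cause was not tested.

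The replicate number as a block gave 365, 260, 1059, 721, 1158 and 1843 for the pairwise counts and 151, 476 and 66 for shared calls. Same-numbered libraries correlated above 0.1 in 6 of 18 pairs (-0.176 to 0.267), and 8 of 12 libraries, not all, correlated best with one of their own number. This is a hint from the data, not the design, so the numbers were not taken as pairs.

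For 277 values of named genes and 5732 alternatives, 5087 kept direction and side of the threshold, 624 lost the call, 19 gained it and 2 reversed: Notch1 in combined against Notch1-titled libraries (-0.046 to 0.41 without each library, negative without Notch1-titled replicate 3) and Zmiz1 in Notch1-titled against control libraries (-0.39 under quantile normalization), neither called. The cause was not tested. The 2-fold minimum accounts for 143 of the lost calls and single left-out libraries for 366. Naming groups by title, robust variances and the leaving out of short noncoding RNA genes were not tabulated for single genes.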

Other observations

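All tests in this part were chosen only after the result was seen. Genes of protein folding in the endoplasmic reticulum were higher with the Notch1 mutant. In a list of 16 ER chaperones and folding enzymes written after Hspa5 and Sdf2l1 had been seen to rise, 13 rose and 3 were not called in Notch1-titled against control libraries (median 0.63, camera adjusted p = 5.59e-18, and 0.00212 with an estimated correlation). Pdia6, a disulfide isomerase, rose by 0.94 and Hyou1, a chaperone of the HSP70 family, by 0.78. Hsp90b1, Manf and Calr rose by 0.75, 0.79 and 0.55. In combined against Zmiz1-titled libraries 13 rose again (median 0.98), with Hyou1 and Pdia6 at 1.31 each, Creld2 at 1.23 and Pdia4 at 1.17. In Zmiz1-titled against control libraries 0 passed in limma and 1 had an unadjusted p under 0.05 (median 0.01). In combined against Notch1-titled libraries 4 rose, 14 did adjusted over the list alone, and the median was 0.32. The list was found from these data and is not independent evidence. Its camera values were adjusted over this list and the HIF target list alone. In the interaction 0 of 16 genes were called in limma, 9 had an unadjusted p under 0.05, and 7 passed adjusted over the list alone. The list itself was called there (median 0.33, camera adjusted p = 3.54e-16, and 0.00151 with an estimated correlation). Growth or culture differences between the groups were not tested.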
